A study of Mus musculus with 6 samples.

How the data were processed

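RNA was sequenced from cancer-associated fibroblasts sorted out of orthotopic mouse lung tumours, 3 libraries with surface MHC class II (apCAFs 1, 2 and 3) and 3 without (nonapCAFs 4, 5 and 6). Per the labels, tumours were pooled, both populations were sorted side by side in independent experiments, and the gate took large cells negative for CD45, CD31, EPCAM and the mCherry tumour reporter and positive for PDPN and PDGFRA. The submitters' processing notes name Trim Galore, Bowtie2 and DESeq2 and the mm10 genome build, without roles or versions; the counter, the annotation and the strand setting are not given in the sources used here. Of the gene identifiers in the files, 55117 of 55298 were found in GENCODE M21 (GRCm38), and 99.5% of those had identical coordinates there. Coordinates below are those of the files.

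The values deposited per library are gene counts that the authors normalized between libraries and rounded to whole numbers, per the file headers, and they are treated here as a score in place of raw counts. Their totals run from 77960347 in nonapCAFs 6 to 93330791 in apCAFs 3, but they are not sequencing depths, which are unknown. Of the whole numbers from 1 to 30, 8 never occur in apCAFs 3 and 3 never occur in apCAFs 2, as happens when values are scaled and then rounded, so reads could not be recovered. No counting interval is given for this reason. The authors' deposited table also holds, per the file headers, a p-value and an adjusted p-value per gene from DESeq2, a fold change as a ratio of normalized counts, its log2, and the GC percent of each gene. The GC percent was not used. The table of all genes holds no mitochondrially encoded gene, so the list of 13 such genes fixed as a sign of RNA quality was not tested.

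The main test had been written for raw counts, with a fallback for normalized values; the fallback was used because the files held normalized values. limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) with group as the only term, without a variance trend and without robust estimation, on the 36443 genes above 0 in at least 1 library. The other 18855 genes were at 0 in all libraries. P-values were two-sided, Benjamini-Hochberg adjusted over all tested genes, and called at 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of genes with low values; SE is limma's moderated standard error. The labels number the libraries 1 to 3 and 4 to 6 and do not say which share an experiment, so no experiment term entered the fit. Where the text gives adjusted p-values, they are from limma unless a gene list or another test is named.

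In all, 33 gene lists were fixed before the data were examined: 18 of pathways and fibroblast states and 15 of other cell types and RNA quality. The 32 lists with measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list. Genes named in the text follow a rule fixed before the data were examined. It takes the sort markers; the 10 largest rises and falls among called genes whose groups do not overlap, with an average log2 CPM of at least 2, from values scaled to library totals, and a symbol that is not a clone or predicted name; and up to 4 called members of each list by smallest p, or the 2 most abundant members where fewer than 2 passed. Genes outside the rule are marked as such. In the list of largest rises, Mir5107 lies within Cd74 on the same strand, so the reads of this pair cannot be told apart.

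apCAFs 1 and 2 differed from each other by an SD of 0.238 in log2 ratio over the 17829 genes with a mean value of at least 100, and nonapCAFs 4 and 5 by 0.246, against 0.479 to 0.708 for the other pairs within a group. The median of the squared difference over the sum was 3.87 and 2.82 for these close pairs, above the 0.455 that counting noise gives for raw counts. Repeat preparations from a single sort would also exceed it, and these values are scaled, so the statistic does not show separate sorts. The libraries were kept apart because the labels list them as separate samples. An analysis with each close pair averaged was added.

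The fit was tested on simulated data drawn 3 times with the real genes' means and spread, with 200 genes of at least 100 in mean value changed by known folds. Genes changed 2-fold were called in 28% to 34% of cases, 4-fold in 76% to 80%, 8-fold in 82% to 92% and 16-fold in 86% to 92%, and median estimates lay within 0.04 of the true log2 change. The fit also called 60 to 80 unchanged genes per draw, out of 200 to 221 called in all, which is more than the adjusted threshold allows. Of these false calls, 52 to 74 per draw had a mean value under 10, where rounding to whole numbers leaves few distinct values. Per draw, 0 or 1 had a mean value of at least 100. The draws treated the libraries as independent and did not carry over the likeness within the close pairs or other links between libraries. The detection rates and counts of false calls therefore hold for independent libraries and may not apply to the real ones.

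Set before the data were examined were repeats with pseudocounts of 0.1 and 5, a filter on low values, leaving out each library, an experiment term under each of the 6 possible pairings, and the estimated correlation. Chosen after the data were seen were repeats with a variance trend, 4 other scalings, a filter at a mean value of 100, a term for apCAFs 3 and nonapCAFs 6, leaving out apCAFs 1 and 2 or apCAFs 3 and nonapCAFs 6, averaging the close pairs, and the class II list without the 3 chain genes of the sorted protein.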

Results

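Gene expression was measured by RNA-seq in fibroblasts sorted from orthotopic mouse lung tumours, in 3 libraries of MHC class II-positive cells (apCAFs, for antigen-presenting cancer-associated fibroblasts) and 3 libraries of MHC class II-negative cells (nonapCAFs). The single comparison the design implies asks which genes set the class II-positive fibroblasts apart from their class II-negative neighbours. Values are the authors' normalized counts, given as mean ± SD (n = 3), and sequencing depth is unknown. Tumours were pooled before sorting, so a library does not stand for a single animal.

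The genes behind the sort followed the labels. H2-Aa (chromosome 17, 34282744 to 34287823), which encodes the class II alpha chain, had 15455 ± 5796 in apCAFs and 215.3 ± 33.3 in nonapCAFs, a 69.0-fold difference (log2 6.11, SE 0.30, limma adjusted p = 0.00643). H2-Ab1 was 54.3-fold and H2-Eb1 78.5-fold higher, and all 3 apCAFs libraries exceeded all 3 nonapCAFs libraries for each. Because class II protein defined the gate, these genes check the labels and are not an independent finding. Of the positive sort markers, Pdpn was 6.65-fold higher in apCAFs (11221 ± 4565 against 1612 ± 209, limma adjusted p = 0.0183), while Pdgfra had 57636 ± 27207 against 18935 ± 2243 and did not pass (limma adjusted p = 0.0855). Of the genes for the proteins used to exclude cells, none passed in limma. The leukocyte gene Ptprc lay between 22 and 65 in apCAFs and between 2 and 34 in nonapCAFs. The endothelial gene Pecam1 lay between 20 and 129 in apCAFs and between 50 and 85 in nonapCAFs. The epithelial gene Epcam read 181, 209 and 21 in apCAFs 1, 2 and 3 and 3 to 13 in nonapCAFs (limma adjusted p = 0.13). In the authors' deposited table Epcam was higher in apCAFs (log2 4.1, DESeq2 adjusted p = 4.96e-05), while Pecam1 did not pass (DESeq2 adjusted p = 0.805).

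**Figure D1:**
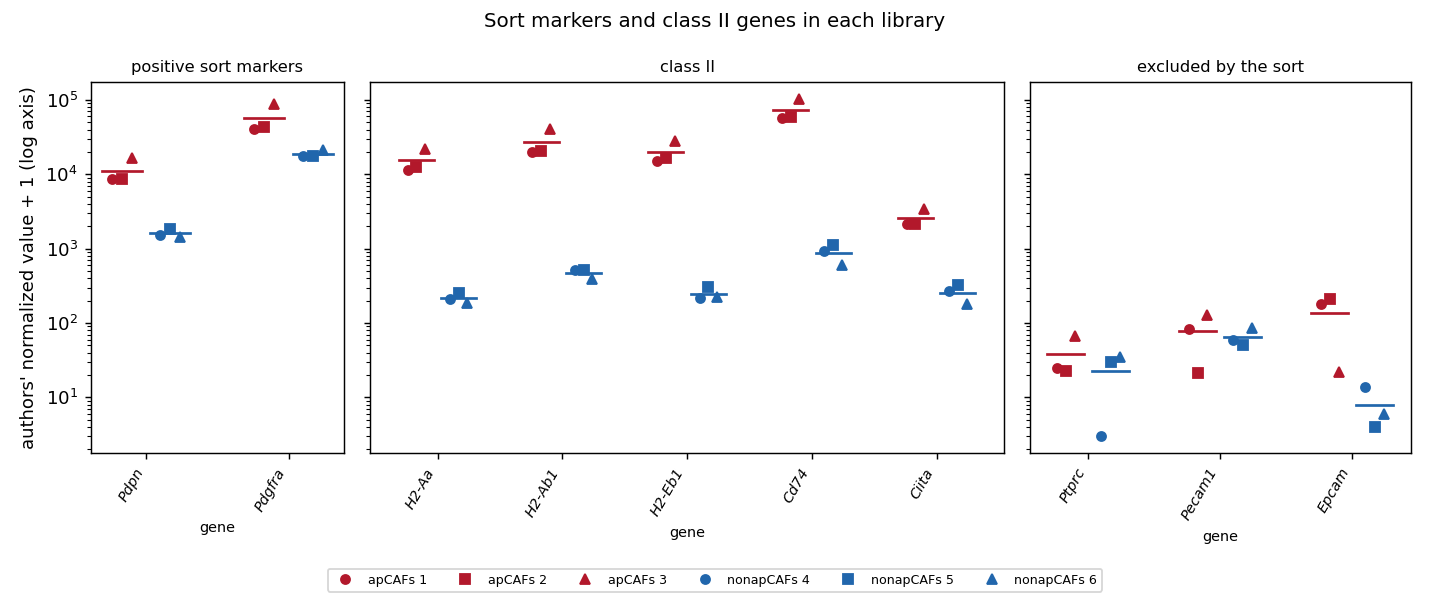
Authors' normalized value plus 1 on a log axis for sort markers and class II genes, with a point per library and a bar at each group's mean. H2-Aa separates the groups 69.0-fold, while Ptprc stays at or under 65 in every library.

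Under the authors' scaling, most called genes were higher in apCAFs. Of 36443 genes tested, limma called 1602, of which 1425 were higher and 177 lower in apCAFs. The median log2 fold change of all tested genes was -0.04. At an unadjusted p under 0.05, 4764 genes lay higher and 2257 lower, but 3947 and 4349 with values divided by library totals, 3776 and 4938 with quantile-normalized values, 4190 and 3719 with median-centred values, and 4550 and 2653 with upper-quartile-centred values. Chil1, which encodes a chitinase-like secreted protein, showed the largest rise among called genes above the naming rule's abundance limit, from 45.3 ± 26.0 to 3935 ± 1104 (log2 6.57, SE 0.57, limma adjusted p = 0.0128). After it came Cd74, the invariant chain that chaperones class II molecules (82.6-fold), the 3 class II chain genes, and genes not part of antigen presentation: Lrrn4 (60.9-fold), Gpm6a (47.6-fold), Upk3b (40.0-fold) and the VEGF receptor gene Kdr (38.5-fold). Vtcn1 (76.8-fold) and Cldn3 (44.4-fold), named for their lists, changed as much but lay under that limit. Among higher genes, 597 with a mean value of at least 100 changed at least 4-fold, and no gene of that abundance was called at least 4-fold lower.

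In the main fit the lower genes were few and mostly faint, but their number depended on the fit: limma called 430 lower when only genes with a mean value of at least 100 were tested, and 490 lower with a variance trend, both chosen after the data were seen. Of the 177, 145 had a mean value under 10, the range in which simulated data gave most false calls, and 12 had a mean value of at least 100; of the 1425 higher genes, 110 had a mean value under 10. The falls that met the naming rule were L1cam, a neural cell adhesion molecule (262.3 ± 4.0 in apCAFs against 895.7 ± 157 in nonapCAFs, log2 -1.75), Nbeal2 (1050 ± 11 against 2709 ± 687, log2 -1.34) and Stra6, a retinol transporter (1385 ± 200 against 2855 ± 155, log2 -1.05), with limma adjusted p = 0.0148, 0.0357 and 0.0348. L1cam overlaps Arhgap4.

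The limma calls depended on how the libraries were treated as replicates. With an experiment term, limma called 0 genes under each of the 6 possible pairings (5316 to 6680 genes at an unadjusted p under 0.05), and it called 0 with apCAFs 1 and 2 averaged and nonapCAFs 4 and 5 averaged (4700 genes at an unadjusted p under 0.05). A balanced pairing leaves every fold change as it is by construction and changes only the error. That error then has fewer degrees of freedom than the 4 of the main fit, so lost calls do not show smaller differences. H2-Aa stayed between 5.72 and 6.69 log2 over all alternatives while its adjusted p reached 0.194. With a term for apCAFs 3 and nonapCAFs 6, chosen after the data were seen, limma called 2490 genes. Without apCAFs 3 it called 1791 genes, without apCAFs 1 411, without apCAFs 2 310, without nonapCAFs 4 464, without nonapCAFs 5 499 and without nonapCAFs 6 810, and the share of higher genes, 89.0% in all libraries, was 58.4% without nonapCAFs 4, 60.3% without nonapCAFs 5 and 78.9% with quantile-normalized values. Without nonapCAFs 4 the higher calls dropped to 271 and the lower calls were 193, while 3796 genes lay higher and 1479 lower at an unadjusted p under 0.05. The authors' deposited table lists 5842 genes at an adjusted p under 0.05, of which 3960 are higher in apCAFs; it has 1198 of the 1602 genes among them, each with the same sign, and gives no adjusted p for the other 404.

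Antigen presentation genes beyond the sorted chains were also higher. In the class II list, 9 of 15 genes rose (10 adjusted over the list alone) and none fell, with a median log2 fold change of 3.33 (camera adjusted p = 8.59e-11, and adjusted p = 0.13 with an estimated correlation). Without H2-Aa, H2-Ab1 and H2-Eb1, a repeat chosen after the data were seen, 6 of 12 genes were called higher (7 adjusted over the list alone) with a median of 1.66 (camera adjusted p = 5.16e-07, and adjusted p = 0.13 with an estimated correlation). Besides the sorted chains and Cd74, the called genes, all named outside the rule, were H2-Eb2, Ciita and 3 peptide-loading genes. The peptide-loading genes were H2-DMa (3.50-fold), H2-DMb1 (10.2-fold) and H2-DMb2 (13.1-fold). Ciita, the transcriptional activator of class II genes, was 10.1-fold higher (limma adjusted p = 0.0141). H2-Eb2 was faint, at 19, 9 and 42 in apCAFs 1, 2 and 3 and at 0 in every nonapCAFs library. A gate on class II protein can itself select cells that express Cd74, Ciita, H2-Eb2 and the H2-DM genes. Their rise is therefore not independent of the sort. The lysosomal protease genes Ctss and Ctsl and the thiol reductase gene Ifi30, also outside the rule, did not pass. In the class I list, 6 of 15 genes rose (11 adjusted over the list alone) with a median of 0.60 (camera adjusted p = 2.05e-09, and adjusted p = 0.13 with an estimated correlation). H2-K1 was 3.12-fold, H2-T23 2.88-fold, H2-Q4 3.60-fold and the peptide transporter gene Tap1 2.69-fold higher; reads of class I genes can be split between near-identical copies, and Tap1 overlaps Psmb9.

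Interferon-inducible genes rose together with them. In the interferon-gamma list 12 of 20 genes were higher (16 adjusted over the list alone, median 1.19, camera adjusted p = 9.85e-12, and adjusted p = 0.13 with an estimated correlation), among them the GTPase genes Gbp6 (3.20-fold), Gbp2 (2.30-fold), Gbp3 (2.28-fold) and Igtp (2.30-fold). In the type I interferon list 13 of 20 were higher (18 adjusted over the list alone, median 1.22, camera adjusted p = 8e-14, and adjusted p = 0.13 with an estimated correlation), and the called genes with the smallest p were Irf7 (5.02-fold), Ifit3 (4.11-fold), Oasl2 (2.87-fold) and the RNA sensor gene Ifih1 (3.03-fold). Gbp genes are close paralogs, Igtp overlaps Irgm2 and Irf7 overlaps Phrf1, so their individual values are less certain.

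Complement genes were among the most abundant that differed. In the complement list 11 of 17 genes rose (12 adjusted over the list alone, with 1 lower), with a median of 2.04 (camera adjusted p = 1.47e-09, and adjusted p = 0.206 with an estimated correlation). C3, the central complement protein, had 416703 ± 163703 in apCAFs and 53887 ± 12848 in nonapCAFs (7.51-fold). Cfb was 8.27-fold, C2 4.84-fold and C1s1 4.24-fold higher. The C1q chain genes, named outside the rule, did not pass: C1qa lay between 56 and 165 across the 6 libraries.

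Genes for signals to immune cells differed in part. Of 16 costimulatory and inhibitory ligand genes 4 rose (8 adjusted over the list alone, median 0.75, camera adjusted p = 0.000145, and adjusted p = 0.13 with an estimated correlation): Vtcn1, an inhibitory B7 family member (291.3 ± 40.8 against 3.67 ± 3.79), Cd80, a costimulatory one (563.7 ± 63.1 against 203.3 ± 14.4), Nectin2 (5.48-fold) and Lgals9 (1.79-fold). Of 26 chemokine genes 4 rose (7 adjusted over the list alone, median 1.12, camera adjusted p = 6.64e-06, and adjusted p = 0.13 with an estimated correlation): Cxcl16 (5.46-fold), Cxcl9 (5.13-fold), Cxcl14 (3.15-fold) and Ccl8 (3.03-fold). In the lymphoid tissue stroma list 2 of 11 rose (8 adjusted over the list alone, median 1.63, camera adjusted p = 2.41e-07, and adjusted p = 0.13 with an estimated correlation), Bst1 (11.9-fold) and the lymphocyte survival cytokine gene Il7 (3.10-fold). In the NF-kB list 1 of 16 rose (4 adjusted over the list alone, median 0.46, camera adjusted p = 0.00468, and adjusted p = 0.50 with an estimated correlation), the adhesion gene Icam1 (6.95-fold). Without nonapCAFs 6 the NF-kB list was not called (median 0.02, camera adjusted p = 0.22). The abundant Nfkbia had 88873 ± 23983 in apCAFs and 88979 ± 36376 in nonapCAFs, and Cxcl1 82817 ± 34992 and 86368 ± 44502.

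Matrix genes were higher as a group. Of 22 structural matrix genes 11 rose (18 adjusted over the list alone, with 1 lower, median 1.35, camera adjusted p = 3.75e-11, and adjusted p = 0.206 with an estimated correlation), including the fibrillar collagen genes Col1a1 (3.08-fold), Col1a2 (3.51-fold) and Col5a2 (3.77-fold) and the crosslinking enzyme gene Lox (4.37-fold). Of 19 matrix protease and inhibitor genes 2 rose (10 adjusted over the list alone, with 1 lower, median 0.73, camera adjusted p = 0.00094, and adjusted p = 0.206 with an estimated correlation), and both were inhibitors, Timp3 (6.16-fold) and Timp1 (3.42-fold). In the myofibroblastic list 3 of 18 rose (10 adjusted over the list alone, median 0.71, camera adjusted p = 0.000175, and adjusted p = 0.358 with an estimated correlation), the contractile genes Tagln (5.02-fold) and Myl9 (3.71-fold) and the collagen gene Col12a1 (3.23-fold). In the inflammatory fibroblast list 3 of 18 rose (5 adjusted over the list alone, median 0.65, camera adjusted p = 0.000818, and adjusted p = 0.168 with an estimated correlation), C3, the acute-phase gene Saa3 (25.0-fold) and Lcn2 (9.73-fold).

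Markers of both kinds of resident lung fibroblast were higher in apCAFs as lists, with few single genes called. In the alveolar fibroblast list 1 of 14 rose (1 adjusted over the list alone, median 1.04, camera adjusted p = 0.0021, and adjusted p = 0.358 with an estimated correlation), Gpc3 (7.09-fold), while Plin2 had 8545 ± 266 and 8955 ± 547 and Lpl 8734 ± 5514 and 3280 ± 1461. In the adventitial list 2 of 12 rose (7 adjusted over the list alone, median 0.94, camera adjusted p = 0.00094, and adjusted p = 0.142 with an estimated correlation), Dpp4 (8.77-fold) and Ly6a (2.26-fold).

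Proliferation and metabolism genes gave few calls. In the cell cycle list 0 of 22 genes passed in limma, over all genes or over the list alone, although all lay below 0 (median -0.41, camera adjusted p = 0.00122, and adjusted p = 0.545 with an estimated correlation); Top2a had 22490 ± 9189 and 27815 ± 3153, and Mki67 15715 ± 5064 and 23121 ± 3113. Much of this came from apCAFs 3: Top2a read 27276, 28297 and 11896 in apCAFs 1, 2 and 3 and 24202 to 30008 in nonapCAFs. Without apCAFs 3 the list's median was -0.12 (camera adjusted p = 0.0465). Of 18 measured glycolysis and hypoxia genes 0 passed (2 higher adjusted over the list alone; camera adjusted p = 0.314), and of 22 oxidative phosphorylation genes 0 passed (camera adjusted p = 0.372).

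**Figure D2:**
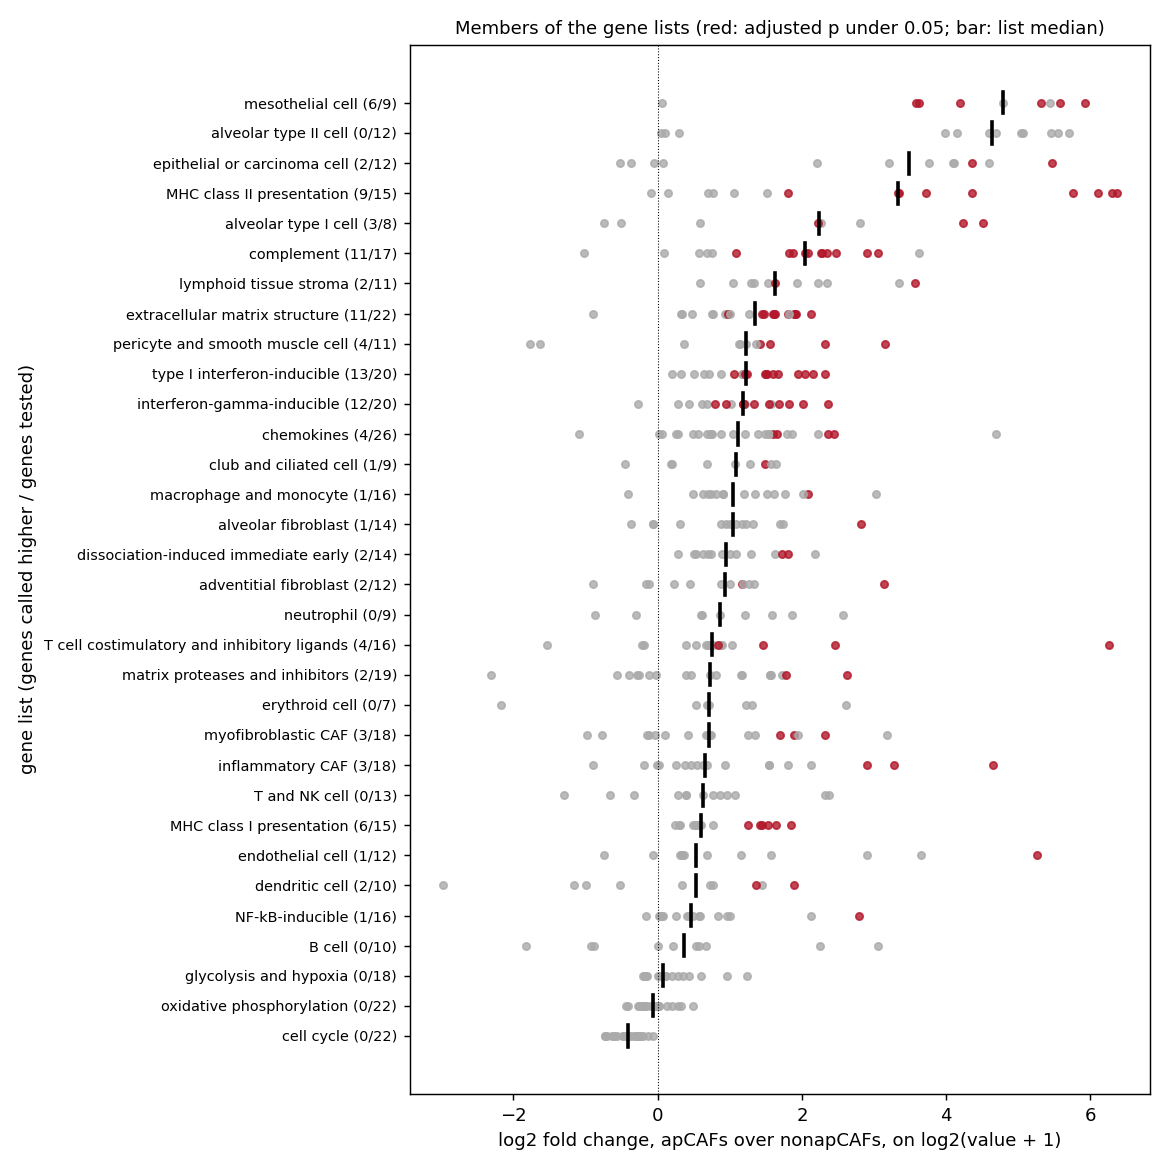
Log2 fold change of apCAFs over nonapCAFs for each measured member of the gene lists, red where limma called it, with a black bar at each list's median. The mesothelial list has a median of 4.79 and the cell cycle list a median of -0.41.

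Markers of mesothelial cells, which line the lung surface, were higher in apCAFs. Of 9 mesothelial genes 6 rose (8 adjusted over the list alone, median 4.79, camera adjusted p = 2.38e-08, and adjusted p = 0.119 with an estimated correlation). Msln, the gene for mesothelin, had 10488 ± 1466 in apCAFs and 950.3 ± 508 in nonapCAFs (11.9-fold, limma adjusted p = 0.0178), Upk1b was 12.3-fold higher, and Lrrn4, Gpm6a and Upk3b lay above every nonapCAFs library in each apCAFs library. Bnc1, named outside the rule, had 3410 ± 594 and 3247 ± 114. In the pericyte and smooth muscle list 4 of 11 rose (8 adjusted over the list alone, with 1 lower, median 1.23, camera adjusted p = 0.000186, and adjusted p = 0.20 with an estimated correlation): Des (8.92-fold), Kcnj8 (4.99-fold), Abcc9 (2.95-fold) and Notch3 (2.68-fold).

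Surfactant transcripts of alveolar type II cells were abundant in apCAFs 1 and 2 and not in apCAFs 3. Sftpc, named outside the rule, read 48853, 40491 and 226 in apCAFs 1, 2 and 3 and 124 to 185 in nonapCAFs. In the type II list 0 of 12 genes passed in limma (0 adjusted over the list alone) against a median of 4.64 (camera adjusted p = 0.00277, and adjusted p = 0.50 with an estimated correlation), and the members with the highest average log2 value over all 6 libraries, Abca3 (4570 ± 282 and 3726 ± 200) and Etv5 (4303 ± 851 and 3966 ± 558), lay close in both groups. Sftpb (13826, 10327 and 72) and Sftpa1 (9646, 8755 and 35), named outside the rule, exceeded both of these in apCAFs 1 and 2. Without apCAFs 3 the type II list's median was 7.055 (camera adjusted p = 3.39e-11). In the broader epithelial list 2 of 12 rose (6 adjusted over the list alone, median 3.48, camera adjusted p = 0.00122, and adjusted p = 0.413 with an estimated correlation), Krt19 (20.4-fold) and Cldn3 (44.4-fold), both high in all 3 apCAFs libraries. In the type I list 3 of 8 rose (5 adjusted over the list alone, median 2.24, camera adjusted p = 0.00348, and adjusted p = 0.206 with an estimated correlation), Aqp5 (22.9-fold), Clic5 (18.9-fold) and Akap5 (4.67-fold). In the club and ciliated list 1 of 9 rose, Cyp2f2 (2.81-fold), and camera gave adjusted p = 0.144, against 0.00769 without apCAFs 3 and 0.0453 without nonapCAFs 4; the abundant Tppp3 had 2443 ± 1446 and 3035 ± 1345.

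**Figure D3:**
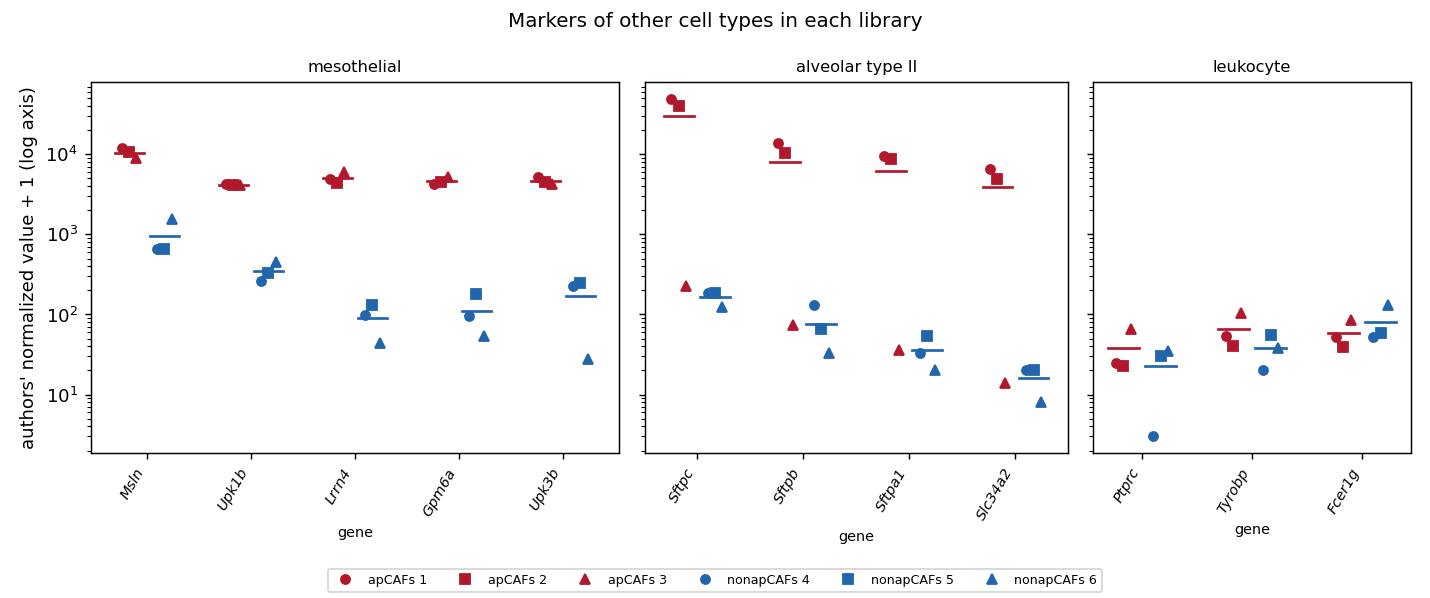
Authors' normalized value plus 1 on a log axis for mesothelial, alveolar type II and leukocyte markers, with a point per library and a bar at each group's mean. Mesothelial markers are high in all 3 apCAFs libraries, Sftpc reads 48853 and 40491 in apCAFs 1 and 2 but 226 in apCAFs 3, and Ptprc and Tyrobp stay at or under 104 in every library.

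Leukocyte lists held few called genes. In the macrophage list 1 of 16 rose (2 adjusted over the list alone, median 1.05, camera adjusted p = 0.00122, and adjusted p = 0.358 with an estimated correlation), Cd14 (4.24-fold); Lyz2, which type II cells also express, read 9898, 9470 and 640 in apCAFs 1, 2 and 3. In the dendritic cell list 2 of 10 measured genes rose, the transcription factor genes Irf8 (2.58-fold) and Batf3 (3.70-fold), with camera adjusted p = 0.386. Adjusted over the list alone, 3 were higher and 1 lower. Itgax (249 against 545, limma adjusted p = 0.0658) and Clec9a (656 against 1141, limma adjusted p = 0.337), named outside the rule, lay lower without passing over all genes. No B cell gene of 10, T and NK cell gene of 13 measured or neutrophil gene of 9 passed in limma (camera adjusted p = 0.63, 0.216 and 0.113), where list-alone adjustment gave 2, 0 and 1 higher. In the endothelial list 1 of 12 rose, Kdr (median 0.53, camera adjusted p = 0.0108, and adjusted p = 0.248 with an estimated correlation), and without apCAFs 1 the list was not called (camera adjusted p = 0.0622). Leaving out a library also added list calls: the T and NK list without apCAFs 2 (camera adjusted p = 0.0338) and the neutrophil list without nonapCAFs 6 (camera adjusted p = 0.0473). In the immediate early list, a sign of tissue dissociation, 2 of 14 rose (8 adjusted over the list alone, median 0.95, camera adjusted p = 1.78e-06, and adjusted p = 0.206 with an estimated correlation), Nr4a1 (3.51-fold) and Dusp1 (3.30-fold). No erythroid gene of 7 passed (camera adjusted p = 0.562), and Hbb-bs read 2053 in apCAFs 3 and 2177 in nonapCAFs 6 against 7 to 210 in the other libraries.

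With the preset correlation, camera called 24 of 32 lists, 23 toward higher and 1 toward lower values. With an estimated correlation camera called 0 lists, with 9 at an unadjusted p under 0.05 and a smallest adjusted p of 0.119.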

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

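Settings other than those planned were chosen after the data were seen: the variance trend, the filter at a mean value of 100, the other scalings, the averaging, the term for apCAFs 3 and nonapCAFs 6, leaving out pairs of libraries, and the class II list without its 3 sorted chain genes (median 1.66). The labels do not say which libraries share an experiment, so each of the 6 possible pairings was fitted. Each pairing term leaves fewer degrees of freedom than the main fit. Under each, limma called 0 genes, 0 higher and 0 lower (5316 to 6680 genes at an unadjusted p under 0.05). Camera called 24 or 25 lists. Averaging apCAFs 1 with 2 and nonapCAFs 4 with 5 also gave 0 genes, 0 higher and 0 lower (4700 genes at an unadjusted p under 0.05), with fewer samples in the fit. Leaving out each library in turn gave 310 to 1791 genes, 254 to 1601 higher and 56 to 198 lower, and 23 to 25 lists. A variance trend gave 3453 genes (2963 higher, 490 lower), of which 1448 were among the 1602. Testing fewer genes, those with a mean value of at least 100, gave 2748 (2318 higher, 430 lower). A term for apCAFs 3 and nonapCAFs 6 gave 2490 (2275 higher), and leaving both out 2489 (377 lower). Leaving out apCAFs 1 and 2, which have surfactant RNA, gave 4575 (2797 higher, 1778 lower), 963 of them among the 1602; this leaves a lone apCAFs library that is assumed to vary like nonapCAFs. There the alveolar type II list's median was -0.15, camera adjusted p = 0.737, and the reversal follows from the missing libraries; 7 other lists lost their calls. Of these, the medians of the epithelial (0.54), type I (0.84) and NF-kB (0.13) lists fell. Those of the myofibroblastic (0.84), alveolar fibroblast (1.39), endothelial (1.18) and inflammatory (0.61) lists stayed close or grew, so these losses do not show that the surfactant libraries drove them. Quantile normalization gave 281 lower genes; the cause was not tested. Pseudocounts of 0.1 and 5, the filter on low values and the remaining scalings kept the counts of called genes within 1.5 times. The lower genes themselves varied more: of the 177, 149 stayed with a pseudocount of 0.1, 164 with the filter and 78 with a pseudocount of 5. Of the 1425 higher genes, 1380 stayed with a pseudocount of 5. Rescaling to library totals shifted the median fold change by -0.15 log2, and quantile normalization by -0.12. Estimating the correlation left 0 lists, with 9 at an unadjusted p under 0.05 in camera. Alternatives planned for raw counts (other size factors, other count models and count filters) were not run, because the values are normalized. Depth is unknown, so its limit on faint genes cannot be given.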

Other observations

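Gene families, grouped by symbol stem after the data were seen, were tested with a one-sided Fisher's exact test for called higher genes, over protein-coding genes with a mean value of at least 10. Of 284 families of at least 8 measured genes 6 passed Benjamini-Hochberg adjustment. Of their called genes, those already in the fixed lists numbered 10 of 14 for the H2 stem, 4 of 7 for Gbp, 7 of 11 for C, 2 of 7 for Ifi, 4 of 10 for Col and 0 of 5 for Apol. The genes named here fall outside the naming rule. In the apolipoprotein L family 5 of 10 genes rose (Fisher's exact test, adjusted p = 0.0297). Apol11a read 142, 104 and 394 in apCAFs 1, 2 and 3 and 0, 3 and 7 in nonapCAFs 4, 5 and 6. Its 57.0-fold rise therefore rests on very low nonapCAFs values. Apol11b rose from 27.0 ± 9.85 to 781.3 ± 543, Apol6 by 2.27-fold, and Apol9a by 2.32-fold and Apol9b by 2.05-fold, which are near-identical copies. In the collagen family 10 of 41 rose (Fisher's exact test, adjusted p = 0.0371), including the basement membrane chain genes Col4a6 (7.77-fold), Col4a4 (3.65-fold), Col4a5 (2.32-fold) and Col4a2 (1.85-fold), beside Col11a1 (3.54-fold) and Col15a1 (2.34-fold). Fisher's exact test treats genes as independent, which genes of a family are not, so these p-values can be too small and do not stand for replicates. The C stem mixes complement genes with C1qtnf1, C1qtnf4 and C1qtnf5 and is not a single family.

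The tests that set the macrophage list and the alveolar type II list over all libraries against the class II list, and the splits for the count of genes, were written before the data were seen; the other tests below were chosen after. The first pattern is the rise of class II genes. Leukocyte RNA was not excluded by its planned test: the macrophage list's median of 1.05 lay within the MAD of 2.43 around the class II list's median of 3.33. The macrophage, dendritic and B cell markers together had a median of 0.73 with a MAD of 0.72. This is not below the class II list by more than both spreads. The class II list's spread is wide because its members range from Cd74 (log2 6.37) to Ctsl (log2 -0.10). With so wide a spread neither test can decide, and leukocytes stay open as a source. The gate excluded CD45, and Ptprc (22 to 65) and Tyrobp (39 to 104) stayed low in apCAFs against 57814 to 102314 for Cd74. Type II cells, which express class II genes themselves, met their planned prediction, with a list median of 4.64. The macrophage list met the same wide rule, so this does not decide for type II cells either. With surfactant transcripts abundant in apCAFs 1 and 2, type II RNA may contribute there despite the EPCAM gate. In apCAFs 3 the type II list lay at -0.15 log2 against the nonapCAFs mean while the class II list lay at 3.52, which argues against that source in this library.

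The second pattern is the rise of mesothelial markers. A smaller share of fibroblasts in the class II-positive gate than in the class II-negative gate would lower fibroblast markers. The alveolar and adventitial lists together instead had a median of 1 with a MAD of 0.44. Of the 26 genes 3 were called higher and 0 lower. Only 177 of all 36443 tested genes were called lower, so the lack of lower calls says little. The share of fibroblasts in nonapCAFs is not known, so the higher median does not exclude other cells beside fibroblasts in apCAFs. Mesothelial cells that passed the gate for PDPN and PDGFRA beside fibroblasts would raise mesothelial markers, and 6 of 9 were called higher with Msln at 10488. A mesothelial programme in the fibroblasts would give the same values, so these cannot be told apart in bulk RNA.

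The third pattern is the excess of higher over lower genes. Among called genes the excess remained under 4 other scalings, where the lowest share of higher genes was 78.9%. These scalings moved the median log2 fold change by only -0.03 to -0.15, so they could hardly reverse changes large enough to be called. The share was lower without nonapCAFs 4 (58.4%) or without nonapCAFs 5 (60.3%). At an unadjusted p under 0.05 the share, 67.9% under the authors' scaling, ran from 43.3% with quantile normalization to 63.2% with upper-quartile centring. Equalizing or centring the libraries itself pulls small changes toward an even split, so this leaves open whether the authors' scaling made the excess among all genes. Biology was not tested apart from the group itself.

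The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. In each comparison 1 split, the real one, gave a result as large: 1602 genes against a highest other of 1, 1425 higher genes against 1, 177 lower genes against 1, and 24 lists against 16. Each of the other splits still sets 2 libraries of a group against 1, so part of the group difference remains in it, and the up to 16 lists called there cannot be assigned to other structure. Deviations from the group means correlated across genes at 0.47 between apCAFs 3 and nonapCAFs 6, where unrelated libraries would give 0 on average. Genes vary together, so a single pair of unrelated libraries can depart from 0, and how far was not measured. The correlations of the other pairs add little to the 0.47, since deviations sum to 0 within a group and the close pairs are nearly alike. apCAFs 3 and nonapCAFs 6 also stood apart in haemoglobin genes, with sums of 6300 and 6599 against 21 to 608 in the other libraries. Cxcl1 read 42569 and 34984 in them against 99862 to 112428 in the others. These values link apCAFs 3 and nonapCAFs 6 but do not show which libraries share an experiment.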
